A study of Sus scrofa with 12 samples.

How the data were processed

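Gene expression was measured by RNA sequencing in unconverted minipig fibroblasts and in induced neurons at days 4, 10 and 28 of conversion, with 3 libraries in each of 4 groups. Per the labels, RNA was prepared on a Maxwell RSC instrument, libraries were sequenced on a BGISEQ-500, and reads were processed with Trimmomatic, HISAT2 2.1.0 and featureCounts 1.6.3 against Sscrofa11.1. The labels do not state strand use, the handling of reads with several matches, or the annotation release. The deposited count table holds raw counts, whole numbers of reads per Ensembl gene, for 31907 genes. The deposited TPM table holds counts divided by gene length and scaled to the same total in each library. The ratio of counts to TPM implied 1 length per gene: over 12670 genes the median coefficient of variation of that length across libraries was 0.00822. Gene symbols were those of the annotation supplied for this build and were joined by Ensembl ID. 15029 IDs had a symbol, 12718 of them among the genes tested. Genes without a symbol entered all counts of genes but no list.

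Libraries were grouped by the labels. Analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Of the 31907 genes, 3750 had no count in any library. The edgeR filter filterByExpr, with its minimum count of 10 and minimum total of 15, left 17577 genes. All 12 libraries were scaled by TMM and fitted together with the edgeR quasi-likelihood model in its robust form, with the group as the sole term and 8 residual degrees of freedom. Each of 5 comparisons was a contrast of that fit, and a gene changed where its Benjamini-Hochberg adjusted p was under 0.05. The standard error (SE) of a log2 change is its size over the root of its quasi-likelihood F, not a fitted value. Total counts per library appear with the results.

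Gene lists were written from general knowledge before the data were examined, 41 lists with 734 genes, of which 599 were tested. A gene may stand in more than 1 list. Lists were tested with camera at its preset correlation of 0.01 and adjusted over all lists. Genes are named in the text by a rule set before the data were examined. In each comparison it names ASCL1, MAP2, TUBB3, PTBP1, REST and COL1A1. It also names the 5 largest rises and falls by fitted log2 change, an order that rests on the prior count where counts are few, among changed genes with a symbol, at least 5 CPM in the higher group and no overlap of libraries between groups. Last, it names up to 4 members of each described list with the smallest p-values. Genes named in the text are a subset of these, picked with their values in view. List members named because they moved against their list, or were among 5 or fewer of a kind, were chosen after their values were seen, as was the gene with the most counts. ASCL1 and REST had no ID with that symbol and were left out. Figures show the genes and lists of the text.

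The tools were tested on simulated data with the spread and depth of these libraries and known changes of 1.5-, 2-, 4- and 8-fold in 50 genes each. For day 28 against fibroblasts edgeR called 1, 26, 48 and 50 of them, and 7 of 16510 unchanged genes. DESeq2 called 6, 35, 49 and 50, and 32. The limma trend test on log2 values called 1, 22, 47 and 50, and 9. For day 10 against day 4 edgeR called 3, 31, 43 and 48, and 3 of 17044. DESeq2 called 9, 37, 45 and 49, and 25, and limma 1, 26, 45 and 49, and 4. In both settings camera called a list of 20 genes changed 2-fold and none of 40 random lists. Lists of co-varying genes, changes in most genes and an outlying control were not tested.

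Alternatives set before the data were examined were DESeq2 size factors or library size alone in place of TMM, no filter on low counts, the DESeq2 Wald test, and a limma trend test on log2(TPM + 1). The others were a fit of the 6 libraries compared, a block for the replicate number, leaving out each library of the groups compared in turn, and for lists an estimated correlation. Chosen after the data were seen were fibroblast replicate 2 as the sole control, the 9 induced-neuron libraries alone, and the contrasts between days without fibroblast replicate 2. Where a group is left with 1 library, that library is assumed to vary like the other groups. The 5 comparisons of induced neurons and fibroblasts leave out day 28 against day 4, which served only to test whether changes from fibroblasts differed between days. Values of genes at 0 or at 1 to 3 counts in a group are given as bounds or ratios because fitted changes of such genes depend on the prior count. These use counts summed over a group's libraries and their summed scaled depth, so ratios can differ from those of the mean CPM.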

Results

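The data are RNA sequencing counts per gene from cells of Göttingen minipigs, a small laboratory breed of pig (Sus scrofa). Fibroblasts of wild-type phenotype, from biopsy at an age of 19 weeks, were compared with induced neurons, cells converted directly from fibroblasts without a stem-cell stage. Conversion used the microRNAs miR-9/9* and miR-124 and the neuronal transcription factor Ascl1. The medium of the induced neurons also held CHIR99021, which activates Wnt signalling by inhibiting GSK3, and SB-431542, LDN-193189 and A-83, which inhibit receptors of the TGF-beta and BMP families. Forskolin and db-cAMP, which raise cAMP signalling, the growth factors GDNF and NT3, LM-22A4 and the histone deacetylase inhibitor valproic acid completed it. There were 4 groups of 3 libraries, unconverted fibroblasts and induced neurons at days 4, 10 and 28. The labels do not say whether the 3 libraries of a group are separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

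Total counts per library ran from 10728783 to 28149736. In replicate order they were 15752367, 10728783 and 26274586 for fibroblasts and 17039811, 16080629 and 28149736 for day 4. At day 10 they were 14919045, 17156998 and 14653403, and at day 28 17400939, 14994106 and 13282102. Levels are given in CPM after TMM scaling, as the mean ± SD of 3 libraries, and log2 changes as the edgeR estimate ± SE. For a gene at 0 in all 3 libraries of a group, the fold is a lower bound taken against a floor of 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Floors and intervals cover counting error only. Members of a gene list are counted as rising or falling over all genes tested, and counts adjusted over the list alone are given where they differ. A list changed where its camera test, which asks whether its genes moved relative to all others, had an adjusted p under 0.05. Where no second camera p is given, the call holds with an estimated correlation between genes.

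Converted cells and fibroblasts parted along the first principal component of log2 CPM, which held 78.8% of the variance. The second component held 9.86%. One gene without a symbol (ENSSSCG00000048719) took 9.14% to 17.4% of all counts in the 9 induced-neuron libraries. The files do not say whether it encodes a messenger or a structural RNA. It took 0.388%, 11.2% and 0.565% in fibroblast replicates 1, 2 and 3. Genes without a symbol held 9.27%, 25.3% and 9.64% there, and 21.6% to 31.3% in induced neurons. Mitochondrial mRNAs held 4.14%, 1.53% and 4.29%, and 2.00% to 4.16% in induced neurons. So replicate 2 differed from 1 and 3, but on the first 2 shares it lay in the range of induced neurons. Each comparison with fibroblasts is therefore also given with replicate 2 as the sole control and with replicates 1 and 3.

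**Figure D1:**
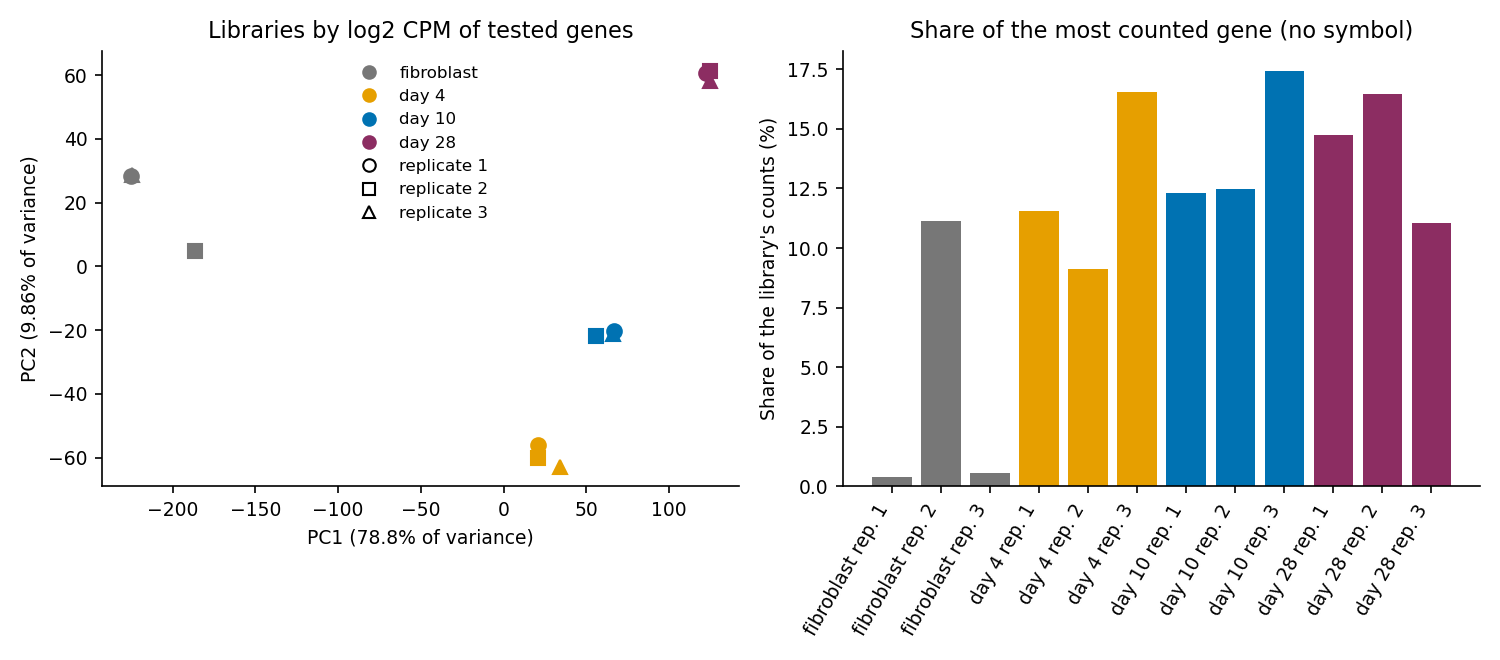
Left, the 12 libraries on the first 2 principal components of log2 CPM, coloured by group with 1 symbol per replicate. Right, each library's percent of counts held by the gene most counted over all 12. Fibroblast replicates 1, 2 and 3 stand at 0.388%, 11.2% and 0.565%.

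The comparison of day 4 with fibroblasts asks which genes differ at the earliest time sampled. TUBB3 (ENSSSCG00000002639), a neuronal beta-tubulin, rose from 39.6 ± 8.55 to 394 ± 119.5 CPM (log2 change 3.32 ± 0.24). MAP2 (ENSSSCG00000016151; Sscrofa11.1 chromosome 15, 112156578 to 112462932), a dendritic microtubule protein, rose from 0.280 ± 0.0636 to 14.2 ± 1.67 CPM (log2 change 5.57 ± 0.23). PTBP1 (ENSSSCG00000013421; chromosome 2, 77551562 to 77563153), a repressor of neuronal splicing and a reported target of miR-124, fell from 461 ± 152 to 116 ± 7.56 CPM (log2 change -1.99 ± 0.22). COL1A1 (ENSSSCG00000036135; chromosome 12, 26379087 to 26397180), which encodes a chain of type I collagen, fell from 3648 ± 590.0 to 829 ± 116 CPM (log2 change -2.14 ± 0.21). By edgeR, the largest adjusted p of these 4 genes was 6.84e-06. The annotation gave no position for TUBB3 under that symbol. ASCL1 and REST have no entry under their symbols in the count table and were not analysed here.

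Pan-neuronal and presynaptic genes rose at day 4. Of 24 pan-neuronal genes tested, 20 rose, 3 fell and 1 did not pass (camera adjusted p = 1.84e-16). ELAVL3, a neuronal RNA-binding protein, rose from 0.552 ± 0.269 to 333 ± 49.4 CPM (log2 change 9.28 ± 0.31). CHGA, a protein of secretory granules, rose from 1.30 ± 0.437 to 544 ± 146 CPM (log2 change 8.64 ± 0.32). The members that fell were SCG2, UCHL1 and DPYSL3. SCG2, another secretory granule protein, fell from 3619 ± 1725 to 40.4 ± 8.27 CPM (log2 change -6.49 ± 0.42). All 25 presynaptic genes tested rose (camera adjusted p = 6.17e-22). The vesicle GTPase RAB3C rose from 0.0756 ± 0.0285 to 30.8 ± 2.40 CPM (459-fold, interval 157 to 2228), and the adhesion protein NRXN1 rose from 0.107 ± 0.0336 to 62.7 ± 12.6 CPM (log2 change 9.03 ± 0.26). Of the genes valued here, the largest edgeR adjusted p was 5.00e-08. For DPYSL3 the edgeR call ended with library-size scaling and in a fit of the 6 libraries compared (adjusted p = 1.32e-05 to 0.154 over 14 alternatives).

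Glutamate receptor, ion channel and proneural genes were higher too, while the GABA and glycine receptor list was not called (11 rose, 1 fell and 4 did not pass, or 12 up and 1 down adjusted over the list alone, camera adjusted p = 0.101, but 0.0218 with no filter). Of 25 postsynaptic and glutamate receptor genes tested, 23 rose, 1 fell and 1 did not pass (camera adjusted p = 4.16e-12; 0.0610 with estimated correlation). CAMK2A, a kinase of the postsynaptic density, rose from 0.356 ± 0.0367 to 25.9 ± 1.46 CPM (log2 change 6.13 ± 0.17), and the kainate receptor subunit GRIK2 rose from 0.0631 ± 0.109 to 42.9 ± 1.01 CPM (log2 change 8.79 ± 0.36). Of 29 voltage-gated ion channel genes tested, 26 rose, 2 did not pass and 1 fell (camera adjusted p = 8.85e-12; 0.105 with estimated correlation). The calcium channel CACNA1A rose from 0.545 ± 0.217 to 60.7 ± 13.9 CPM (log2 change 6.74 ± 0.27), and the sodium channel SCN5A rose from 0.0250 ± 0.0433 to 30.1 ± 5.14 CPM (1373-fold, interval 246 to 54258). DLG4 and CACNA1D fell in these lists. Of 19 proneural genes (transcription factors and Notch ligands) tested, 16 rose and 3 did not pass, or 17 up and 0 down adjusted over the list alone (camera adjusted p = 6.55e-06; 0.0879 with estimated correlation). NEUROD4, a basic helix-loop-helix factor of neurogenesis, rose from 0.0914 ± 0.0150 to 57.6 ± 4.0 CPM (log2 change 9.20 ± 0.21), and the Notch ligand DLL3 rose from 0.498 ± 0.296 to 237 ± 63.5 CPM (log2 change 9.04 ± 0.34). All edgeR adjusted p-values of the valued genes were 1.03e-09 or less. For DLG4 the edgeR call ended with library-size scaling, with no filter, on the deposited TPM, in a fit of the 6 libraries compared, with a replicate block, with fibroblast replicate 2 as the sole control and without any 1 of fibroblast replicates 1 and 3 and day 4 replicates 1 and 2 (adjusted p = 0.000574 to 0.960 over 14 alternatives).

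Genes responding to Wnt, BMP, TGF-beta and Notch signalling moved at day 4. The cAMP response list was not called (4 rose, 10 fell and 3 did not pass, or 5 up and 10 down adjusted over the list alone, camera adjusted p = 0.122, but 0.0400 with no filter and 0.0105 without fibroblast replicate 2). Of 15 Wnt response genes tested, 12 rose and 3 fell (camera adjusted p = 0.00444; 0.133 with estimated correlation). AXIN2 and APCDD1, feedback inhibitors of Wnt signalling, rose from 23.9 ± 0.774 to 177 ± 13.5 CPM (log2 change 2.89 ± 0.12) and from 0.318 ± 0.191 to 54.7 ± 8.89 CPM (log2 change 7.23 ± 0.33). The members that fell were MYC, CCND1 and DKK1. Of 13 BMP response genes tested, 8 fell, 3 did not pass and 2 rose (camera adjusted p = 0.000201; 0.0879 with estimated correlation). ID1 and ID3, inhibitors of helix-loop-helix factors, fell from 416 ± 82.9 to 20.3 ± 0.365 CPM (log2 change -4.36 ± 0.18) and from 671 ± 178 to 22.4 ± 2.1 CPM (log2 change -4.91 ± 0.23), while HEY1 and BAMBI rose. Of 16 TGF-beta response genes tested, 13 fell, 2 did not pass and 1 rose (camera adjusted p = 1.20e-08; 0.134 with estimated correlation). CCN1 fell from 875 ± 268 to 18.2 ± 1.43 CPM (log2 change -5.58 ± 0.25) and SERPINE1 fell from 296 ± 67.5 to 11.3 ± 2.26 CPM (log2 change -4.72 ± 0.23), while PMEPA1 rose. Of 11 Notch response genes tested, 8 rose, 2 did not pass and 1 fell (camera adjusted p = 0.000254). HEYL and DTX1 rose from 0.107 ± 0.0336 to 89.7 ± 4.77 CPM (log2 change 9.54 ± 0.22) and from 0.138 ± 0.121 to 56.0 ± 11.5 CPM (log2 change 8.41 ± 0.32), while HEY2 fell. With edgeR the adjusted p of the valued genes was at most 4.52e-09. For PMEPA1 the edgeR call ended in a fit of the 6 libraries compared and with fibroblast replicate 2 as the sole control (adjusted p = 8.56e-08 to 0.0837 over 14 alternatives).

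Fibroblast, contractile and cell-cycle genes were lower. Of 34 fibroblast identity genes tested, 30 fell, 3 did not pass and 1 rose, or 2 up and 30 down adjusted over the list alone (camera adjusted p = 9.98e-07; 0.389 with estimated correlation). FN1 (fibronectin) fell from 19084 ± 6081 to 1172 ± 169.7 CPM (log2 change -4.03 ± 0.32). FBLN1, a matrix protein of this list, rose from 64.3 ± 33.5 to 201 ± 16.1 CPM (log2 change 1.64 ± 0.35). COL6A3, FBLN2 and SPARC did not pass, at log2 changes of 0.67 ± 0.30, -0.45 ± 0.35 and -0.39 ± 0.30. Without fibroblast replicate 2, FBLN2 and SPARC passed as falls, while with replicate 2 as the sole control FBLN2 passed as a rise (adjusted p = 0.000855 to 0.776 over 14 alternatives and adjusted p = 0.0129 to 0.744 over 14 alternatives, respectively). COL6A3 passed as a rise with library-size scaling, with DESeq2, with fibroblast replicate 2 as the sole control and without day 4 replicate 1 (adjusted p = 0.00203 to 0.164 over 14 alternatives). Of 12 contractile and myofibroblast genes tested, 10 fell and 2 rose (camera adjusted p = 1.64e-07). TAGLN, an actin-binding protein of smooth muscle, fell from 1028 ± 325 to 10.8 ± 1.27 CPM (log2 change -6.57 ± 0.27), while DES and MYH11 rose. All 16 S-phase genes tested fell (camera adjusted p = 3.71e-12; 0.0918 with estimated correlation). The replication helicase subunit MCM4 fell from 103 ± 12.1 to 11.4 ± 0.651 CPM (log2 change -3.18 ± 0.13). All 22 G2/M genes tested fell (camera adjusted p = 1.03e-26). CCNB1, the mitotic cyclin B1, fell from 70.2 ± 11.7 to 1.41 ± 0.482 CPM (log2 change -5.65 ± 0.23), and TOP2A fell from 180.4 ± 44.7 to 5.85 ± 0.488 CPM (log2 change -4.95 ± 0.22). The largest edgeR adjusted p of the valued genes that passed was 0.00133.

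The list of reported miR-9 and miR-9* targets was not called (6 rose, 8 fell and 1 did not pass, camera adjusted p = 0.613). Of 16 reported miR-124 targets tested, 12 fell and 4 did not pass (camera adjusted p = 6.18e-05; 0.134 with estimated correlation). Beside PTBP1, its relative PTBP3 fell from 334 ± 23.1 to 109.6 ± 3.90 CPM (log2 change -1.61 ± 0.12), and the phosphatase CTDSP1 fell from 193 ± 15.4 to 53.9 ± 9.22 CPM (log2 change -1.84 ± 0.15). Of 15 neuronal BAF and splicing genes tested, 12 rose and 3 did not pass (camera adjusted p = 1.99e-10; 0.0584 with estimated correlation). Picked by fitted log2 change, SLC5A5 rose from 0 to 30.7 ± 5.35 CPM (at least 433-fold), PKP1 from 0 to 25.4 ± 1.45 CPM (at least 376-fold), NDST4 from 0 to 25 ± 3.27 CPM (at least 378-fold), STUM from 0 to 20.5 ± 4.99 CPM (at least 316-fold) and ARHGDIG from 0 to 19.6 ± 7.21 CPM (at least 264-fold). Picked likewise, TYRP1 fell from 136 ± 25.7 to 0.248 ± 0.0466 CPM (log2 change -9.10 ± 0.40), CENPA from 17.9 ± 9.23 to 0.0405 ± 0.0701 CPM (631-fold, interval 174 to 5215), CDCA5 from 20.6 ± 8.76 to 0.0738 ± 0.0645 CPM (log2 change -7.91 ± 0.59), ACTA2 from 162 ± 4.36 to 0.726 ± 0.0967 CPM (log2 change -7.82 ± 0.22) and CCL11 from 7.04 ± 3.56 to 0.0228 ± 0.0394 CPM (249-fold, interval 68.5 to 2066). TYRP1 is an enzyme of melanin synthesis, CENPA and CDCA5 serve chromosome segregation, ACTA2 is smooth muscle actin and CCL11 is a chemokine. By edgeR, the largest adjusted p of these genes was 5.09e-05.

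In all, 10627 of 17577 genes tested changed with edgeR, 5881 up and 4746 down, and 11317 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 10048 genes (57.2%, against 10% by chance). Library-size scaling gave 7126 up and 3529 down (66.9% up against 55.3%), with the median gene shifted by 0.27 (log2). By camera, 19 of 41 lists changed, 12 up and 7 down, and 5 with an estimated correlation. With fibroblast replicate 2 as the sole control 9481 genes changed, and without it 13573. Of the 10627 calls, 7205 were made in the same direction with both, while 719 genes were called in opposite directions by the 2 sets of controls. The log2 change of PTBP1 was -1.27 with replicate 2 alone and -2.24 without it (edgeR adjusted p = 1.28e-05 and 9.91e-10).

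**Figure D2:**
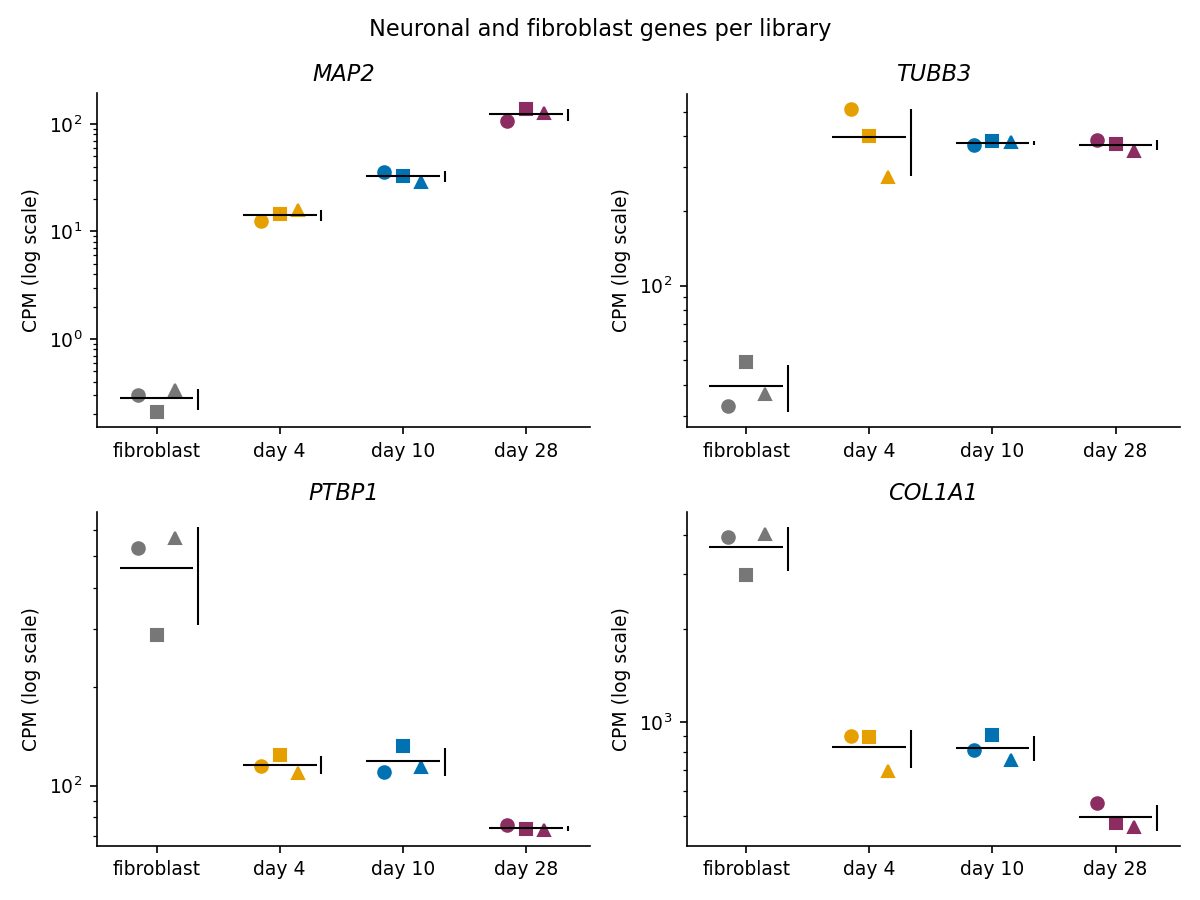
CPM (log scale) of MAP2, TUBB3, PTBP1 and COL1A1 in each library of the 4 groups, with a line at the mean of 3 libraries and a bar for the SD. MAP2 goes from a mean of 0.280 CPM in fibroblasts to 123 CPM at day 28, while TUBB3 stays between 367 and 394 CPM on average from day 4 on.

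The comparison of day 10 with fibroblasts asks which genes differ midway through the period sampled. MAP2 stood at 32.6 ± 3.62 CPM, a log2 change of 6.76 ± 0.23, and TUBB3 at 375 ± 7.34 CPM, a log2 change of 3.25 ± 0.24. PTBP1 stood at 119 ± 11.7 CPM, a log2 change of -1.96 ± 0.22, and COL1A1 at 825 ± 78.6 CPM, a log2 change of -2.14 ± 0.21 (largest edgeR adjusted p of the 4 = 6.77e-06). Of 24 pan-neuronal genes tested, 21 rose and 3 fell (camera adjusted p = 1.18e-20). The neuronal RNA-binding protein ELAVL2 rose from 0.444 ± 0.138 to 212 ± 16.5 CPM (log2 change 8.97 ± 0.24), and the secretory granule protein SCG3 rose from 0.661 ± 0.122 to 109 ± 4.28 CPM (log2 change 7.31 ± 0.19). As at day 4, SCG2, UCHL1 and DPYSL3 fell. All 25 presynaptic genes tested rose (camera adjusted p = 1.44e-28). CPLX2 (complexin 2), which acts in vesicle fusion, rose from 0.680 ± 0.0634 to 147 ± 4.34 CPM (log2 change 7.74 ± 0.20), and the vesicle GTPase RAB3B rose from 1.65 ± 0.204 to 138 ± 2.28 CPM (log2 change 6.40 ± 0.15). Of these examples, the largest edgeR adjusted p was 4.25e-11.

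Receptor, channel, GABAergic and cholinergic lists rose at day 10. The glutamatergic (6 rose, 1 fell and 5 did not pass, or 5 up and 1 down adjusted over the list alone, camera adjusted p = 0.143, but 0.0359 with no filter) and monoaminergic (6 rose, 1 fell and 5 did not pass, camera adjusted p = 0.341) lists were not called. Of 25 postsynaptic and glutamate receptor genes tested, 24 rose and 1 fell (camera adjusted p = 7.08e-17). The NMDA receptor subunit GRIN1 rose from 0.123 ± 0.0594 to 19.0 ± 0.658 CPM (log2 change 7.06 ± 0.27), and DLG4 fell. Of 16 GABA and glycine receptor genes tested, 12 rose, 3 did not pass and 1 fell (camera adjusted p = 0.00122; 0.0902 with estimated correlation). The GABA-A receptor subunits GABRB2 and GABRB3 rose from 0 to 25.8 ± 3.20 CPM (at least 375-fold) and from 0.620 ± 0.205 to 9.96 ± 1.34 CPM (log2 change 4.08 ± 0.23), while GABBR2 fell. Of 29 voltage-gated ion channel genes tested, 25 rose, 3 did not pass and 1 fell (camera adjusted p = 2.76e-13; 0.0767 with estimated correlation). The potassium channel KCNH2 rose from 0.903 ± 0.332 to 51.1 ± 3.45 CPM (log2 change 5.73 ± 0.20), and CACNA1C fell. Of 16 GABAergic genes tested, 10 rose, 4 fell and 2 did not pass (camera adjusted p = 0.000378), and the camera call ended on the deposited TPM (adjusted p = 0.000161 to 0.0795 over 14 alternatives). The GABA transporter SLC6A1 rose from 0.151 ± 0.0571 to 189 ± 18.6 CPM (log2 change 10.35 ± 0.28) and CALB2 (calretinin) rose from 0.605 ± 0.290 to 98.1 ± 3.38 CPM (log2 change 7.44 ± 0.26). Those that fell were SST, NPY, DLX1 and DLX2, the neuropeptide NPY from 234 ± 119 to 1.96 ± 0.194 CPM (log2 change -6.90 ± 0.43). Of 10 cholinergic and motor genes tested, 9 rose and 1 fell (camera adjusted p = 0.000467; 0.0902 with estimated correlation). The motor neuron factor LHX3 rose from 0.0250 ± 0.0433 to 16.8 ± 0.861 CPM (741-fold, interval 133 to 29322) and acetylcholinesterase ACHE rose from 0.746 ± 0.0136 to 12.1 ± 0.669 CPM (log2 change 4.01 ± 0.17), while the choline transporter SLC5A7 fell. All edgeR adjusted p-values of the valued genes were 3.00e-08 or less. For DLG4 the edgeR call ended with library-size scaling, on the deposited TPM, with fibroblast replicate 2 as the sole control and without any 1 of fibroblast replicates 1 and 3 and day 10 replicates 1 and 3 (adjusted p = 0.000285 to 0.857 over 14 alternatives), that for CACNA1C ended with library-size scaling (adjusted p = 0.000106 to 0.0685 over 14 alternatives) and that for DLX2 ended with fibroblast replicate 2 as the sole control (adjusted p = 1.58e-05 to 0.889 over 14 alternatives).

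Inflammatory, glycolysis, G2/M and fibroblast lists were lower at day 10. Those of oxidative phosphorylation (3 rose, 1 fell and 15 did not pass, camera adjusted p = 0.797) and cholesterol synthesis (3 rose, 11 fell and 8 did not pass, camera adjusted p = 0.123, but 0.0137 with no filter) were not called. Of 15 inflammatory secretory genes tested, 10 fell and 5 rose (camera adjusted p = 0.00856; 0.0902 with estimated correlation), and the camera call ended in a fit of the 6 libraries compared (adjusted p = 3.19e-05 to 0.0902 over 14 alternatives). The members that rose were CXCL12, IL6, CDKN2A, CDKN2B and TNFAIP3. For TNFAIP3 the edgeR call ended without any 1 of fibroblast replicate 1 and day 10 replicate 2 (adjusted p = 0.00187 to 0.0643 over 14 alternatives). The chemokine CCL2 fell from 1085 ± 274 to 9.85 ± 0.805 CPM (log2 change -6.78 ± 0.24), and PTGS2, the inducible enzyme of prostaglandin synthesis, fell from 2900.5 ± 867 to 24.9 ± 3.21 CPM (log2 change -6.86 ± 0.43). Of 16 glycolysis genes tested, 11 fell, 3 rose and 2 did not pass (camera adjusted p = 0.0289; 0.568 with estimated correlation), and the camera call ended with fibroblast replicate 2 as the sole control (adjusted p = 0.00124 to 0.568 over 14 alternatives). The lactate exporter SLC16A3 fell from 56.8 ± 5.95 to 12.2 ± 1.90 CPM (log2 change -2.22 ± 0.16), and hexokinase 2 (HK2) fell from 18.4 ± 5.20 to 3.31 ± 0.552 CPM (log2 change -2.48 ± 0.24), while PFKM, HK1 and PFKP rose. All 22 G2/M genes tested fell (camera adjusted p = 3.58e-26). The kinetochore protein CENPF fell from 124 ± 12.2 to 1.12 ± 0.332 CPM (log2 change -6.77 ± 0.21). Of 34 fibroblast identity genes tested, 32 fell, 1 rose and 1 did not pass (camera adjusted p = 3.18e-08; 0.349 with estimated correlation). FBLN1 rose from 64.3 ± 33.5 to 216 ± 27.3 CPM (log2 change 1.74 ± 0.35). With edgeR the adjusted p of the valued genes was at most 0.000798.

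Picked by fitted log2 change, XKR4 rose at day 10 from 0 to 93.1 ± 11.7 CPM (at least 1359-fold), NDST4 from 0 to 40.3 ± 5.35 CPM (at least 593-fold), TMEM130 from 0 to 38.2 ± 4.22 CPM (at least 565-fold), PTPRN2 from 0 to 36.2 ± 2.71 CPM (at least 534-fold) and NAP1L2 from 0 to 32.7 ± 4.63 CPM (at least 484-fold). Picked likewise, ACTG2 fell from 20.7 ± 6.45 to 0 CPM (at least 319-fold), CENPA from 17.9 ± 9.23 to 0 CPM (at least 335-fold), CCL11 from 7.04 ± 3.56 to 0 CPM (at least 133-fold), TROAP from 23.5 ± 12.2 to 0.0225 ± 0.0389 CPM (1291-fold, interval 231 to 51053) and S100A5 from 5.49 ± 1.80 to 0 CPM (at least 98.2-fold). The largest edgeR adjusted p of these 10 genes was 4.01e-05. Over all genes at day 10, 11335 of 17577 genes tested changed with edgeR, 6172 up and 5163 down, and 11865 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 11608 genes (66.0%, against 10% by chance). Library-size scaling gave 7706 up and 3691 down (67.6% up against 54.5%), with the median gene shifted by 0.34 (log2). A fit of the 6 libraries compared gave 4651 up and 5279 down (46.8% up). By camera, 22 of 41 lists changed, 12 up and 10 down, and 7 with an estimated correlation. With fibroblast replicate 2 as the sole control 10096 genes changed, and without it 13960. Of the 11335 calls, 7904 were made in the same direction with both, while 703 genes were called in opposite directions by the 2 sets of controls.

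The comparison of day 28 with fibroblasts asks which genes differ at the latest time sampled. MAP2 reached 123 ± 16.0 CPM, a log2 change of 8.67 ± 0.23, and TUBB3 stood at 367 ± 17.1 CPM, a log2 change of 3.21 ± 0.24. PTBP1 stood at 74.2 ± 1.22 CPM, a log2 change of -2.64 ± 0.22, and COL1A1 at 494 ± 46.5 CPM, a log2 change of -2.88 ± 0.22 (largest edgeR adjusted p of the 4 = 3.87e-07). Of 24 pan-neuronal genes tested, 21 rose and 3 fell (camera adjusted p = 6.98e-20). SCG3 rose from 0.661 ± 0.122 to 267 ± 13.9 CPM (log2 change 8.61 ± 0.20), while SCG2, DPYSL3 and UCHL1 again fell. All 25 presynaptic genes tested rose (camera adjusted p = 8.63e-29). CPLX2 rose from 0.680 ± 0.0634 to 641 ± 36.2 CPM (log2 change 9.86 ± 0.22). All 19 proneural genes tested rose (camera adjusted p = 1.15e-07; 0.0638 with estimated correlation). SCRT1, a zinc-finger repressor of neurons, rose from 0.0158 ± 0.0273 to 32.5 ± 1.96 CPM (1433-fold, interval 257 to 56645). By edgeR, the largest adjusted p of these examples was 3.45e-10. For UCHL1 the edgeR call ended with library-size scaling, on the deposited TPM, with fibroblast replicate 2 as the sole control and without any 1 of fibroblast replicates 1 and 3 and day 28 replicate 2 (adjusted p = 0.000318 to 0.908 over 14 alternatives).

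Receptor genes of glutamate and GABA rose at day 28. Of 25 postsynaptic and glutamate receptor genes tested, 24 rose and 1 fell (camera adjusted p = 9.87e-17). The metabotropic glutamate receptor GRM5 rose from 0.0250 ± 0.0433 to 155 ± 11.7 CPM (6818-fold, interval 1223 to 269331), and DLG4 fell. Of 16 GABA and glycine receptor genes tested, 13 rose and 3 did not pass, or 14 up and 0 down adjusted over the list alone (camera adjusted p = 5.89e-06). GABRB3 rose from 0.620 ± 0.205 to 90.2 ± 1.37 CPM (log2 change 7.26 ± 0.23). Of 29 voltage-gated ion channel genes tested, 26 rose, 2 did not pass and 1 fell, or 27 up and 1 down adjusted over the list alone (camera adjusted p = 3.46e-12; 0.0904 with estimated correlation). The sodium channel SCN8A rose from 4.29 ± 0.194 to 119 ± 14.1 CPM (log2 change 4.80 ± 0.19), while CACNA1C fell. Of the valued genes, the largest edgeR adjusted p was 3.26e-10. For DLG4 the edgeR call ended with library-size scaling and with fibroblast replicate 2 as the sole control (adjusted p = 1.03e-05 to 0.113 over 14 alternatives).

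Genes of several transmitter identities were counted at day 28. Of 16 GABAergic genes tested, 11 rose, 4 fell and 1 did not pass (camera adjusted p = 5.40e-05). SLC6A1 rose from 0.151 ± 0.0571 to 353 ± 17.9 CPM (log2 change 11.25 ± 0.29), the GABA-synthesising enzyme GAD1 rose from 1.22 ± 0.671 to 152 ± 7.28 CPM (log2 change 6.93 ± 0.26) and RELN (reelin) rose from 0.0756 ± 0.0285 to 68.6 ± 9.69 CPM (998-fold, interval 341 to 4843). The members that fell were NPY, SST, DLX1 and DLX2. Of 11 peripheral sensory genes tested, 10 rose and 1 fell (camera adjusted p = 0.000318). TAC1, the precursor of substance P, rose from 0.0158 ± 0.0273 to 27.1 ± 3.71 CPM (1203-fold, interval 216 to 47568), and the ATP-gated channel P2RX3 of sensory neurons rose from 0.0250 ± 0.0433 to 10.7 ± 1.27 CPM (469-fold, interval 83.9 to 18577), while the sodium channel SCN11A fell. Of 12 glutamatergic genes tested, 8 rose, 3 did not pass and 1 fell (list not called, camera adjusted p = 0.0958, but 0.0218 with no filter). The vesicular glutamate transporter SLC17A7 rose from 1.79 ± 0.648 to 43 ± 2.73 CPM (log2 change 4.52 ± 0.28), the cortical factor TBR1 rose from 0.0664 ± 0.0577 to 7.73 ± 0.585 CPM (113-fold, interval 38.3 to 549.6), and SATB2 fell. Of 12 neural progenitor genes tested, 8 rose, 3 fell and 1 did not pass (list not called, camera adjusted p = 0.423). Those that fell were ASPM, PAX6 and PROM1, the progenitor factor PAX6 from 619 ± 251 to 59.1 ± 4.61 CPM (log2 change -3.39 ± 0.27). All edgeR adjusted p-values of the valued genes were 1.75e-07 or less. For DLX2 the edgeR call ended in a fit of the 6 libraries compared and with fibroblast replicate 2 as the sole control (adjusted p = 1.94e-05 to 0.758 over 14 alternatives).

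Fibroblast genes and reported miR-124 targets were lower at day 28. All 34 fibroblast identity genes tested fell (camera adjusted p = 1.30e-12; 0.239 with estimated correlation). FN1 fell from 19084 ± 6081 to 117 ± 6.01 CPM (log2 change -7.35 ± 0.38), and POSTN (periostin) fell from 486 ± 45.6 to 38.6 ± 2.28 CPM (log2 change -3.65 ± 0.16). Of 16 reported miR-124 targets tested, 15 fell and 1 did not pass (camera adjusted p = 2.53e-06; 0.0962 with estimated correlation). PTBP3 fell from 334 ± 23.1 to 37.5 ± 2.98 CPM (log2 change -3.15 ± 0.13), and the aryl hydrocarbon receptor AHR fell from 362 ± 75.5 to 18.0 ± 0.379 CPM (log2 change -4.33 ± 0.20). Of 15 neuronal BAF and splicing genes tested, 14 rose and 1 did not pass (camera adjusted p = 2.50e-10). The neuronal splicing factors RBFOX1 and NOVA2 rose from 0.0158 ± 0.0273 to 24.9 ± 0.509 CPM (1095-fold, interval 196 to 43276) and from 0.135 ± 0.0817 to 17.2 ± 1.25 CPM (log2 change 7.13 ± 0.29). Of 19 oxidative phosphorylation genes tested, 11 rose and 8 did not pass (list not called, camera adjusted p = 0.191, but 0.0276 with no filter and 0.0319 on the deposited TPM). PPARGC1A, a coactivator of mitochondrial biogenesis, rose from 0.359 ± 0.0683 to 82.1 ± 7.58 CPM (log2 change 7.87 ± 0.25), and cytochrome c (CYCS) rose from 48.6 ± 6.19 to 152 ± 15.4 CPM (log2 change 1.64 ± 0.18). With edgeR the adjusted p of the valued genes was at most 4.50e-06.

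Picked by fitted log2 change, XKR4 rose at day 28 from 0 to 310.0 ± 53.6 CPM (at least 4515-fold), TMEM130 from 0 to 138 ± 9.52 CPM (at least 2033-fold), IGSF21 from 0 to 119 ± 10.5 CPM (at least 1755-fold), OPRM1 from 0 to 111 ± 8.41 CPM (at least 1622-fold) and GABRB2 from 0 to 102 ± 6.22 CPM (at least 1491-fold). OPRM1 is the mu opioid receptor. Picked likewise, CHI3L1 fell from 373 ± 244 to 0.144 ± 0.0430 CPM (log2 change -11.29 ± 0.81), TYRP1 from 136 ± 25.7 to 0.104 ± 0.0437 CPM (log2 change -10.29 ± 0.45), SLC2A5 from 33.4 ± 4.43 to 0.0213 ± 0.0368 CPM (1709.7-fold, interval 306 to 67575), S100A4 from 172 ± 86.7 to 0.133 ± 0.118 CPM (log2 change -10.19 ± 0.79) and PRELP from 2287 ± 492 to 2.09 ± 0.249 CPM (log2 change -10.09 ± 0.29). SLC2A5 is a fructose transporter and PRELP a matrix proteoglycan. The largest edgeR adjusted p of these 10 genes was 1.51e-07. Over all genes at day 28, 12619 of 17577 genes tested changed with edgeR, 6698 up and 5921 down, and 12959 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 12789 genes (72.8%, against 10% by chance). Library-size scaling gave 8093 up and 4545 down (64.0% up against 53.1%), with the median gene shifted by 0.36 (log2). By camera, 18 of 41 lists changed, 10 up and 8 down, and 9 with an estimated correlation. With fibroblast replicate 2 as the sole control 12306 genes changed, and without it 14803. Of the 12619 calls, 9933 were made in the same direction with both, while 633 genes were called in opposite directions by the 2 sets of controls.

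**Figure D3:**
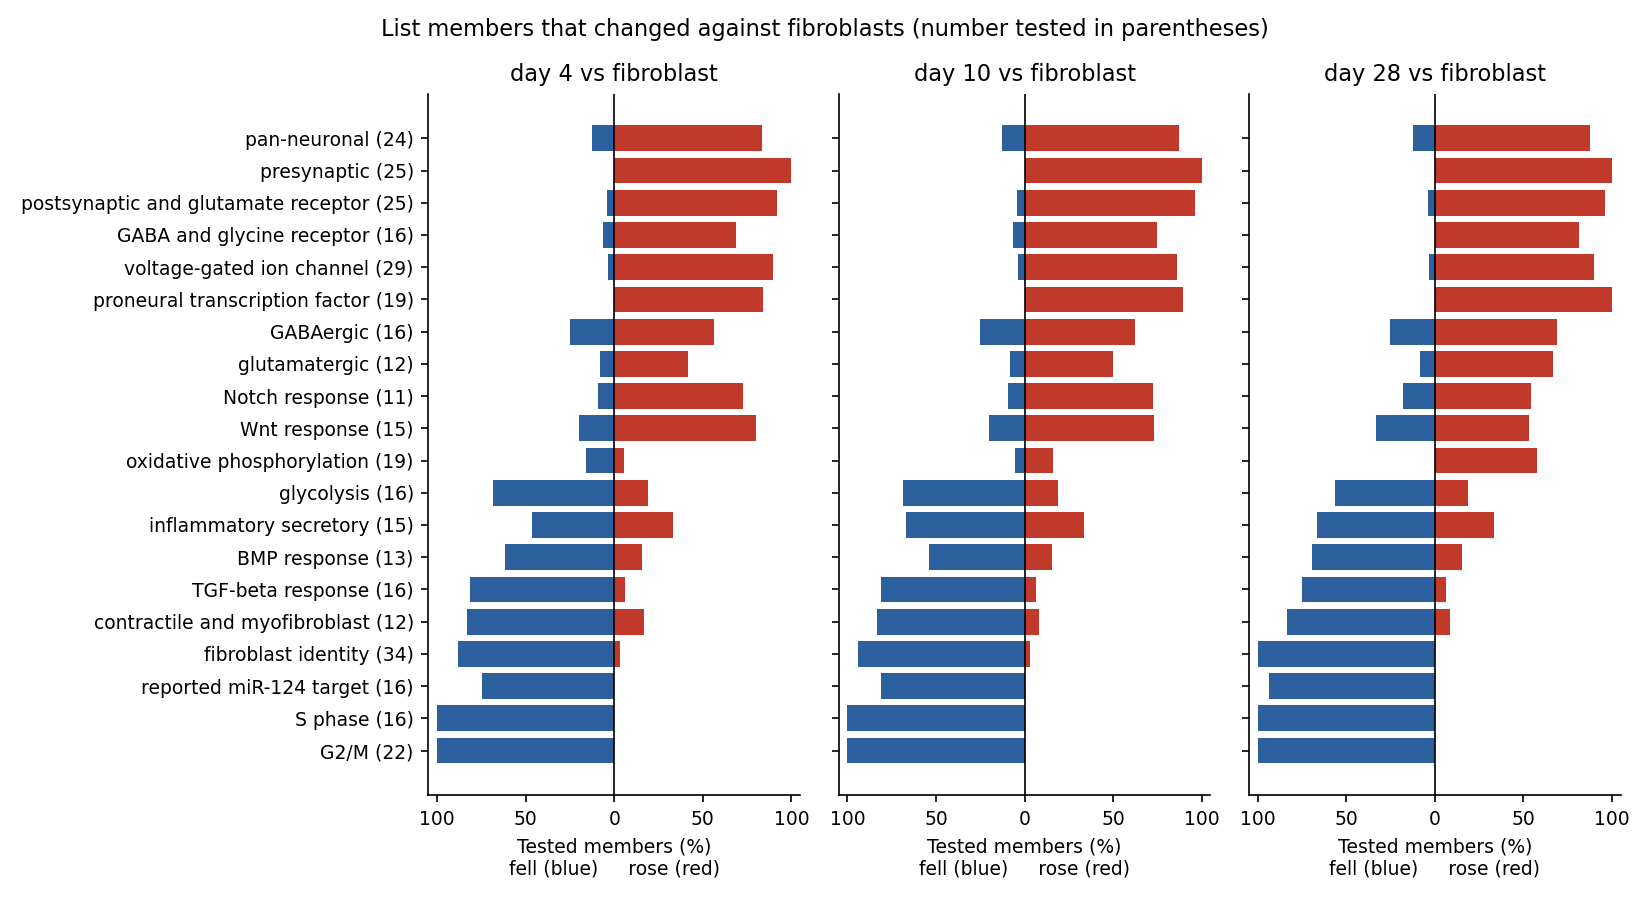
Share of the tested members of 20 fixed gene lists that rose (right, red) or fell (left, blue) against fibroblasts at days 4, 10 and 28, in percent, with the number tested in parentheses. At day 28 all 25 presynaptic genes had risen and all 34 fibroblast identity genes had fallen.

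Calls at day 4 and at day 28 were made largely on the same genes. Of the 17577 genes tested, 9317 were called in the same direction at both days, 5133 up and 4184 down. Lists of the same sizes drawn independently would share 2241 and 1599. Another 174 genes were called in opposite directions. Both comparisons share the 3 fibroblast libraries, too few to leave each comparison at least 2 of its own, so part of the likeness may come from them. Across 15232 genes, the log2 changes had a Pearson correlation of 0.894 and the same sign in 83.5%, against 0.522 and 67.2% on average in 20 simulations of unchanged groups against shared controls. Their covariance was 3.07 against 0.0709, a difference of 3.00. Genes are not independent replicates.

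The comparison of day 10 with day 4 asks what changed early within the converted cells. Some genes of neurons rose: INA, a neuronal intermediate filament protein, rose from 1.78 ± 0.244 to 17.2 ± 1.92 CPM (log2 change 3.29 ± 0.21), and STMN2 (stathmin 2) rose from 24.8 ± 2.75 to 128 ± 8.82 CPM (log2 change 2.37 ± 0.23). MAP2 rose from 14.2 ± 1.67 to 32.6 ± 3.62 CPM (log2 change 1.19 ± 0.15) (largest edgeR adjusted p of the 3 = 0.000330). TUBB3, PTBP1 and COL1A1 did not pass, at log2 changes of -0.071 ± 0.22, 0.034 ± 0.21 and -0.00607 ± 0.20 (edgeR adjusted p = 0.921, 0.965 and 0.995). Of 24 pan-neuronal genes tested, 14 did not pass and 10 rose, or 14 up and 0 down adjusted over the list alone (camera adjusted p = 2.42e-19). The neurofilament NEFL rose from 43.4 ± 7.87 to 173 ± 4.89 CPM (log2 change 2.00 ± 0.19), and SCG3 rose from 39.7 ± 6.09 to 109 ± 4.28 CPM (log2 change 1.46 ± 0.13). Of 25 presynaptic genes tested, 14 rose and 11 did not pass, or 16 up and 0 down adjusted over the list alone (camera adjusted p = 9.99e-30). The synaptic vesicle proteins SYT1 (synaptotagmin 1) and SYN3 (synapsin 3) rose from 1.58 ± 0.236 to 17.3 ± 1.09 CPM (log2 change 3.43 ± 0.17) and from 3.88 ± 0.833 to 21.1 ± 1.16 CPM (log2 change 2.44 ± 0.16). By edgeR, the largest adjusted p of these 4 genes was 6.93e-05.

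Some receptor and channel genes rose as well. Of 25 postsynaptic and glutamate receptor genes tested, 14 rose and 11 did not pass, or 18 up and 1 down adjusted over the list alone (camera adjusted p = 1.81e-19). GRM5 and GRIN1 rose from 3.18 ± 0.880 to 28.6 ± 4.10 CPM (log2 change 3.13 ± 0.22) and from 3.65 ± 0.795 to 19.0 ± 0.658 CPM (log2 change 2.37 ± 0.17). Of 16 GABA and glycine receptor genes tested, 8 rose and 8 did not pass, or 10 up and 0 down adjusted over the list alone (camera adjusted p = 4.38e-12). GABRB3 rose from 1.79 ± 0.313 to 9.96 ± 1.34 CPM (log2 change 2.48 ± 0.18). Of 29 voltage-gated ion channel genes tested, 17 did not pass, 11 rose and 1 fell, or 13 up and 1 down adjusted over the list alone (camera adjusted p = 2.02e-06; 0.162 with estimated correlation). The potassium channel KCNC1 rose from 1.65 ± 0.521 to 9.63 ± 0.917 CPM (log2 change 2.51 ± 0.21), and SCN5A fell from 30.1 ± 5.14 to 13.9 ± 1.53 CPM (log2 change -1.12 ± 0.20). Of these genes, the largest edgeR adjusted p was 0.00415. Other large rises were those of STMN4 from 2.45 ± 0.296 to 38.9 ± 4.63 CPM (log2 change 3.97 ± 0.19), SLC7A14 from 0.454 ± 0.101 to 5.75 ± 0.753 CPM (log2 change 3.68 ± 0.25), LGI1 from 0.465 ± 0.219 to 5.23 ± 1.09 CPM (log2 change 3.50 ± 0.40) and NCAN from 0.766 ± 0.131 to 7.82 ± 0.918 CPM (log2 change 3.37 ± 0.21), with SYT1 the 5 largest of the comparison (largest edgeR adjusted p = 0.000213). NCAN (neurocan) is a proteoglycan of brain matrix.

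Some G2/M, inflammatory, ER stress and Notch response genes fell from day 4 to day 10, while most of each list did not pass. The S-phase list was not called (1 rose and 15 did not pass, camera adjusted p = 0.433). Of 22 G2/M genes tested, 16 did not pass and 6 fell, or 0 up and 9 down adjusted over the list alone (camera adjusted p = 1.04e-06; 0.139 with estimated correlation). CENPF fell from 4.45 ± 0.406 to 1.12 ± 0.332 CPM (log2 change -1.97 ± 0.20), and TOP2A fell from 5.85 ± 0.488 to 1.95 ± 0.483 CPM (log2 change -1.59 ± 0.23). Of 15 inflammatory secretory genes tested, 12 did not pass and 3 fell, or 1 up and 6 down adjusted over the list alone (camera adjusted p = 0.000215; 0.0624 with estimated correlation). These were LIF, CXCL8 and CCL2, of which LIF fell from 71.7 ± 5.13 to 19.9 ± 2.26 CPM (log2 change -1.85 ± 0.29) and the chemokine CXCL8 fell from 96.6 ± 21.9 to 27.8 ± 3.85 CPM (log2 change -1.79 ± 0.31). Of 13 ER stress and amino acid response genes tested, 10 did not pass and 3 fell (camera adjusted p = 0.00288; 0.122 with estimated correlation). CHAC1 fell from 75.5 ± 7.92 to 39.0 ± 1.99 CPM (log2 change -0.95 ± 0.13) and TRIB3 fell from 14.9 ± 3.02 to 6.82 ± 0.660 CPM (log2 change -1.13 ± 0.17), and the cystine transporter SLC7A11 fell by 0.90 (log2). Of 11 Notch response genes tested, 10 did not pass and 1 fell (camera adjusted p = 0.0294; 0.30 with estimated correlation). The gene that fell was HEYL, from 89.7 ± 4.77 to 52.4 ± 1.82 CPM (log2 change -0.78 ± 0.12). Picked by fitted log2 change, S100A4 fell from 5.68 ± 3.19 to 0.411 ± 0.170 CPM (log2 change -3.76 ± 0.71), SLC38A8 from 13.9 ± 4.36 to 1.14 ± 0.305 CPM (log2 change -3.60 ± 0.43), LBP from 62.7 ± 32.1 to 6.51 ± 1.05 CPM (log2 change -3.26 ± 0.37), MFAP4 from 12.9 ± 4.39 to 1.32 ± 0.370 CPM (log2 change -3.26 ± 0.52) and TGM2 from 34.7 ± 4.20 to 4.06 ± 0.757 CPM (log2 change -3.09 ± 0.18). All edgeR adjusted p-values of the genes named were 0.0133 or less. For SLC7A11 the edgeR call ended on the deposited TPM and without any 1 of day 4 replicate 2 and day 10 replicates 2 and 3 (adjusted p = 0.000499 to 0.0854 over 15 alternatives).

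In all, 1336 of 17577 genes tested changed with edgeR, 917 up and 419 down, and 3584 had an unadjusted p under 0.05. The libraries did not overlap for 5558 genes (31.6%, against 10% by chance). By camera, 16 of 41 lists changed, 9 up and 7 down, and 4 with an estimated correlation. The gene count moved with the libraries in the fit and the tool, and was 2184 with DESeq2. It was 665 without day 4 replicate 2 and 653, 802 and 712 without day 10 replicates 1, 2 and 3. Without day 4 replicate 3, which stood apart (chi-square per degree of freedom 124 and 93.4 against 20 for the others), 1226 genes and 20 lists changed, 5 lists gained and 1, cAMP response, lost. The gene count was 3554 without fibroblast replicate 2, 2072 in a fit of the 6 libraries compared (52.6% up against 68.6%) and 3169 in a fit of the 9 induced-neuron libraries.

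The comparison of day 28 with day 10 asks what changed late among the induced-neuron libraries. MAP2 rose from 32.6 ± 3.62 to 123 ± 16.0 CPM (log2 change 1.91 ± 0.15) (edgeR adjusted p = 4.11e-06). TUBB3 did not pass, at a log2 change of -0.032 ± 0.22 (edgeR adjusted p = 0.934). PTBP1 and COL1A1 fell from 119 ± 11.7 to 74.2 ± 1.22 CPM (log2 change -0.68 ± 0.21) and from 825 ± 78.6 to 494 ± 46.5 CPM (log2 change -0.74 ± 0.20) (edgeR adjusted p = 0.0323 and 0.0170). Of 24 pan-neuronal genes tested, 18 rose and 6 did not pass, or 19 up and 1 down adjusted over the list alone (camera adjusted p = 1.25e-10). INA and NEFL rose from 17.2 ± 1.92 to 116 ± 4.35 CPM (log2 change 2.75 ± 0.19) and from 173 ± 4.89 to 719 ± 45.0 CPM (log2 change 2.05 ± 0.19). Of 25 presynaptic genes tested, 19 rose and 6 did not pass, or 21 up and 0 down adjusted over the list alone (camera adjusted p = 8.23e-17). RIMS1, a protein of the presynaptic active zone, rose from 5.94 ± 0.822 to 54.4 ± 2.17 CPM (log2 change 3.19 ± 0.14), and CPLX2 rose from 147 ± 4.34 to 641 ± 36.2 CPM (log2 change 2.12 ± 0.14). With edgeR the adjusted p of these 4 genes was at most 1.39e-05. For PTBP1 the edgeR call ended on the deposited TPM, with a replicate block and without any 1 of day 10 replicates 1, 2 and 3 and day 28 replicates 1 and 2 (adjusted p = 2.62e-06 to 0.120 over 15 alternatives), and the edgeR call for COL1A1 ended without any 1 of day 10 replicates 1 and 2 and day 28 replicate 2 (adjusted p = 5.83e-06 to 0.0792 over 15 alternatives).

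Glutamate and GABA receptor, channel, GABAergic, cholinergic and sensory lists rose late, while the glutamatergic list was not called (3 rose, 1 fell and 8 did not pass, or 4 up and 1 down adjusted over the list alone, camera adjusted p = 0.113). Of 25 postsynaptic and glutamate receptor genes tested, 15 rose, 9 did not pass and 1 fell (camera adjusted p = 1.28e-07; 0.0521 with estimated correlation), the member that fell being GRIA1. Of 10 cholinergic and motor genes tested, 7 rose and 3 did not pass (camera adjusted p = 0.000109). Of 16 GABA and glycine receptor genes tested, 11 rose, 4 did not pass and 1 fell (camera adjusted p = 7.33e-10). GABRB3 and GABRG2 rose from 9.96 ± 1.34 to 90.2 ± 1.37 CPM (log2 change 3.18 ± 0.17) and from 1.15 ± 0.129 to 10.7 ± 1.13 CPM (log2 change 3.22 ± 0.23), while GABRG1 fell. Of 29 voltage-gated ion channel genes tested, 14 rose, 13 did not pass and 2 fell (camera adjusted p = 0.000289; 0.315 with estimated correlation). The potassium channel KCND3 rose from 10.1 ± 1.08 to 60.3 ± 2.38 CPM (log2 change 2.58 ± 0.21), while the calcium channels CACNA1G and CACNA1C fell. Of 16 GABAergic genes tested, 7 rose, 7 did not pass and 2 fell (camera adjusted p = 0.000322). The vesicular GABA transporter SLC32A1 rose from 3.35 ± 0.0869 to 25.1 ± 1.73 CPM (log2 change 2.90 ± 0.23), RELN rose from 11.5 ± 1.43 to 68.6 ± 9.69 CPM (log2 change 2.57 ± 0.15) and PVALB (parvalbumin) rose from 0.265 ± 0.0635 to 4.33 ± 0.245 CPM (log2 change 4.01 ± 0.41), while NPY and CALB2 fell. Of 11 peripheral sensory genes tested, 6 did not pass and 5 rose, or 7 up and 1 down adjusted over the list alone (camera adjusted p = 0.000109). The neurotrophin receptor NTRK2 rose from 2.60 ± 0.256 to 56.1 ± 5.34 CPM (log2 change 4.43 ± 0.30), P2RX3 rose from 0.871 ± 0.147 to 10.7 ± 1.27 CPM (log2 change 3.60 ± 0.30) and TAC1 rose from 4.75 ± 0.310 to 27.1 ± 3.71 CPM (log2 change 2.51 ± 0.23). The largest edgeR adjusted p of the valued genes was 2.78e-05. For GABRG1 the edgeR call ended with DESeq2 and without any 1 of day 10 replicates 1 and 3 and day 28 replicates 1, 2 and 3 (adjusted p = 0.00714 to 0.105 over 15 alternatives), and the call for GRIA1 ended without day 28 replicate 2 (adjusted p = 7.55e-05 to 0.0538 over 15 alternatives).

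Some cAMP response and oxidative phosphorylation genes rose, and some Wnt response, fibroblast identity and reported miR-124 target genes fell. Of 17 cAMP response genes tested, 9 did not pass and 8 rose, or 10 up and 0 down adjusted over the list alone (camera adjusted p = 0.0271; 0.532 with estimated correlation), and the camera call ended without day 10 replicate 1 (adjusted p = 0.00259 to 0.532 over 15 alternatives). VGF, an activity-induced neuropeptide precursor, rose from 48.7 ± 6.85 to 359 ± 44.0 CPM (log2 change 2.88 ± 0.26). Of 19 oxidative phosphorylation genes tested, 11 rose and 8 did not pass (camera adjusted p = 0.00167; 0.532 with estimated correlation). PPARGC1A and CYCS rose from 35.7 ± 1.39 to 82.1 ± 7.58 CPM (log2 change 1.2 ± 0.16) and from 75.1 ± 4.66 to 152 ± 15.4 CPM (log2 change 1.02 ± 0.18). Mitochondrial mRNAs held 2.40 ± 0.417% of counts at day 10 and 3.93 ± 0.313% at day 28 (not tested). Of 15 Wnt response genes tested, 7 fell, 7 did not pass and 1 rose, or 1 up and 8 down adjusted over the list alone (camera adjusted p = 0.000341; 0.193 with estimated correlation). AXIN2 fell from 138 ± 8.36 to 58.0 ± 4.12 CPM (log2 change -1.25 ± 0.12), the Wnt inhibitor NKD1 fell from 77.8 ± 2.91 to 19.3 ± 1.54 CPM (log2 change -2.01 ± 0.21), and RNF43 rose. Of 34 fibroblast identity genes tested, 24 fell and 10 did not pass, or 0 up and 27 down adjusted over the list alone (camera adjusted p = 2.56e-15; 0.213 with estimated correlation). POSTN fell from 162 ± 18.1 to 38.6 ± 2.28 CPM (log2 change -2.07 ± 0.15). Of 16 reported miR-124 targets tested, 8 fell and 8 did not pass (camera adjusted p = 4.48e-05; 0.151 with estimated correlation). AHR fell from 107 ± 15.6 to 18.0 ± 0.379 CPM (log2 change -2.57 ± 0.19). By edgeR, the largest adjusted p of the valued genes was 0.00122. For RNF43 the edgeR call ended without any 1 of day 10 replicates 2 and 3 (adjusted p = 1.62e-06 to 0.0618 over 15 alternatives).

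Some inflammatory and p53 target genes fell and some glial genes rose. Of 15 inflammatory secretory genes tested, 9 did not pass, 5 fell and 1 rose, or 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.00208; 0.0945 with estimated correlation). LIF and IL6 fell from 19.9 ± 2.26 to 0.944 ± 0.267 CPM (log2 change -4.40 ± 0.38) and from 30.1 ± 4.41 to 3.43 ± 0.841 CPM (log2 change -3.13 ± 0.20), as did CCL2, CXCL8 and PTGS2, while the chemokine CCL5 rose. Of 14 p53 response genes tested, 8 fell, 5 did not pass and 1 rose, or 1 up and 10 down adjusted over the list alone (camera adjusted p = 0.0116; 0.371 with estimated correlation). ZMAT3 and TP53INP1 fell from 155 ± 26.3 to 64.4 ± 5.36 CPM (log2 change -1.27 ± 0.19) and from 72.7 ± 16.3 to 18.9 ± 0.487 CPM (log2 change -1.94 ± 0.29), while PLK3 rose. Of 9 oligodendrocyte and Schwann genes tested, 5 rose and 4 did not pass (camera adjusted p = 0.0154; 0.148 with estimated correlation), and the camera call ended in a fit of the 6 libraries compared (adjusted p = 0.0110 to 0.148 over 15 alternatives). The glial factor SOX10 rose from 2.77 ± 0.149 to 14.4 ± 1.18 CPM (log2 change 2.37 ± 0.26) and myelin basic protein MBP rose from 11.3 ± 1.39 to 30.9 ± 1.23 CPM (log2 change 1.46 ± 0.20), beside OLIG2, OLIG1 and FOXD3. Of the valued genes, the largest edgeR adjusted p was 0.000387. For FOXD3 the edgeR call ended with no filter, with a replicate block and without any 1 of day 10 replicates 1 and 3 and day 28 replicates 1, 2 and 3 (adjusted p = 0.00821 to 0.198 over 15 alternatives).

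Picked by fitted log2 change, GALNT14 rose from day 10 to day 28 from 0.123 ± 0.0639 to 14.8 ± 1.42 CPM (log2 change 6.86 ± 0.42), DSCAM from 0.121 ± 0.104 to 11.7 ± 1.77 CPM (log2 change 6.52 ± 0.46), NEUROD6 from 0.0963 ± 0.0908 to 5.12 ± 1.02 CPM (log2 change 5.59 ± 0.61), EXOC3L4 from 0.242 ± 0.105 to 7.71 ± 0.965 CPM (log2 change 4.96 ± 0.32) and CACNG2 from 0.685 ± 0.0492 to 17.9 ± 1.64 CPM (log2 change 4.70 ± 0.40). DSCAM is a neuronal adhesion protein, NEUROD6 a neuronal transcription factor and CACNG2 (stargazin) a subunit of AMPA receptor complexes. Picked likewise, LBP fell from 6.51 ± 1.05 to 0.101 ± 0.0344 CPM (log2 change -5.91 ± 0.63), FBLN1 from 216 ± 27.3 to 4.0 ± 1.15 CPM (log2 change -5.74 ± 0.43), C4A from 97.5 ± 13.9 to 2.75 ± 0.574 CPM (log2 change -5.14 ± 0.30) and C3 from 168 ± 12.9 to 7.68 ± 2.33 CPM (log2 change -4.45 ± 0.29), as did LIF. C3 and C4A are complement components and LBP binds bacterial lipopolysaccharide. The value of C4A is uncertain, since near-identical copies of this gene can occur. All edgeR adjusted p-values of these genes were 0.000104 or less. In all, 5027 of 17577 genes tested changed with edgeR, 2696 up and 2331 down, and 6975 had an unadjusted p under 0.05. The libraries did not overlap for 10849 genes (61.7%, against 10% by chance). By camera, 19 of 41 lists changed, 13 up and 6 down, and 7 with an estimated correlation. The gene count was 3324 without day 10 replicate 2, 8181 without fibroblast replicate 2, 9756 in a fit of the 6 libraries compared and 7687 in a fit of the 9 induced-neuron libraries.

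**Figure D4:**
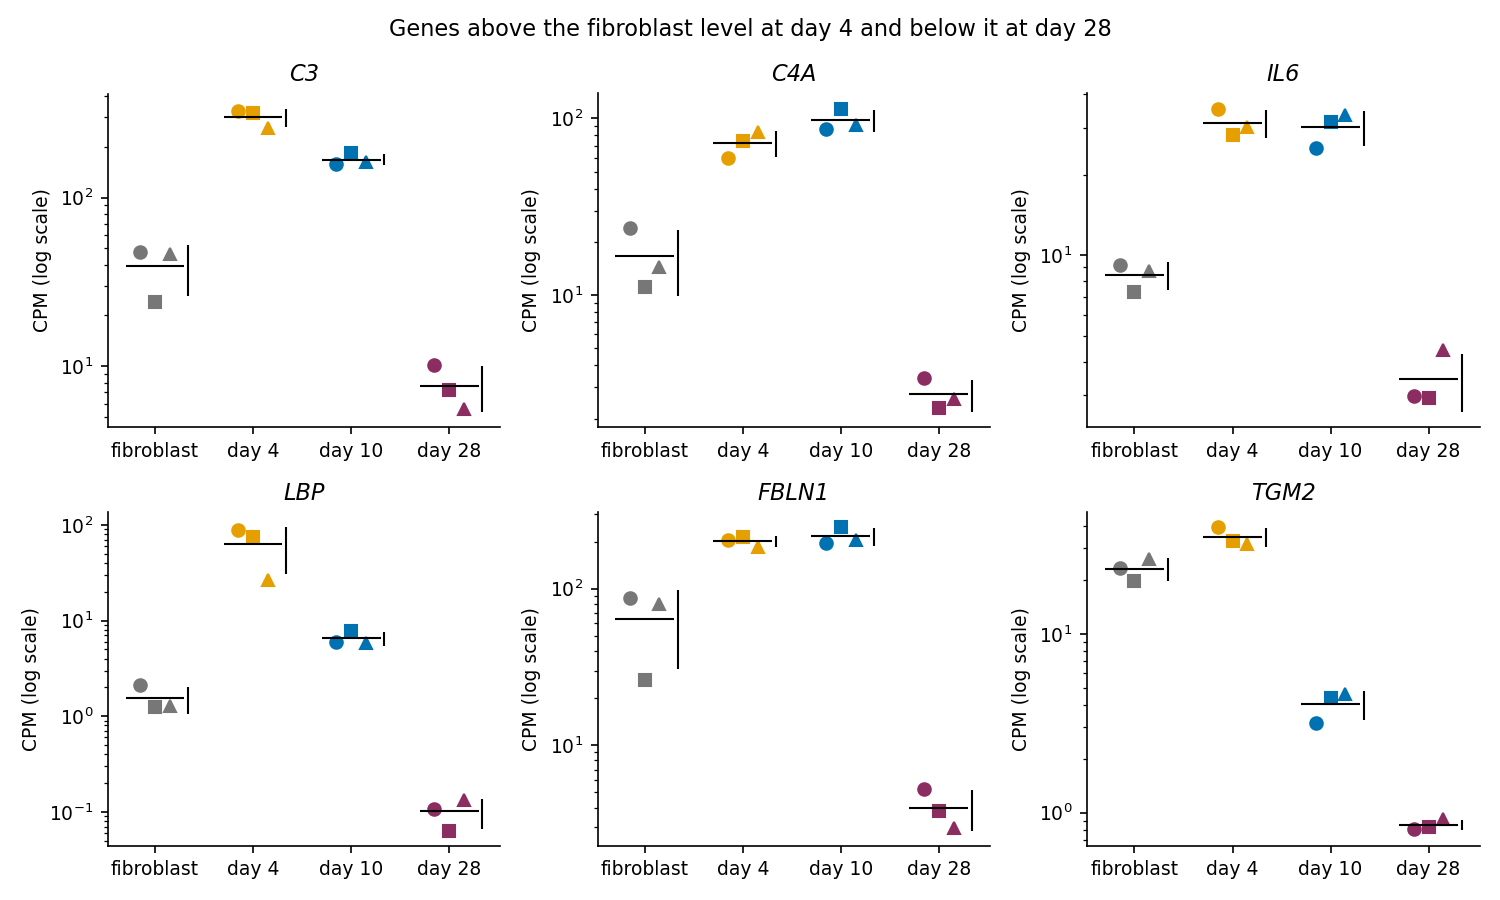
CPM (log scale) of C3, C4A, IL6, LBP, FBLN1 and TGM2 in each library of the 4 groups, with a line at the mean of 3 libraries and a bar for the SD. Mean C3 goes from 39.3 CPM in fibroblasts to 299.7 CPM at day 4 and 7.68 CPM at day 28.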

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

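The tests of induced neurons in fibroblast replicate 2, of a constant share of fibroblast RNA at day 28 and of melanocytes were chosen only after the result was seen, the second and the third after a different criterion for each had not decided, and the third was then also read by library.

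Some genes named in the text changed from fibroblasts in opposite directions at 2 of the days, and an edgeR test of the difference itself passed. Over all genes 174 did so between days 4 and 28, 44 between days 10 and 28 and 6 between days 4 and 10. The values that follow are log2 changes from fibroblasts. ZMAT3 stood at 0.53 at day 4 and -0.97 at day 28, a difference of -1.49 from day 4 to day 28 (adjusted p = 4.53e-05). PLK3 stood at -0.73 at day 4, -0.67 at day 10 and 0.97 at day 28, a difference of 1.70 from day 4 to day 28 (adjusted p = 8.07e-06) and 1.65 from day 10 to day 28 (adjusted p = 2.96e-05); with replicate 2 as the sole control the changes at day 4 and day 10 did not pass (adjusted p = 0.148 and 0.215). C3 stood at 2.92 at day 4, 2.09 at day 10 and -2.36 at day 28, a difference of -5.28 from day 4 to day 28 (adjusted p = 9.90e-08) and -4.45 from day 10 to day 28 (adjusted p = 1.35e-06). IL6 stood at 1.88 at day 4, 1.83 at day 10 and -1.30 at day 28, a difference of -3.18 from day 4 to day 28 (adjusted p = 1.81e-07) and -3.13 from day 10 to day 28 (adjusted p = 1.24e-06). PROM1 stood at 0.84 at day 4 and -2.06 at day 28, a difference of -2.89 from day 4 to day 28 (adjusted p = 6.23e-07). SLC7A11 stood at 0.58 at day 4 and -0.86 at day 28, a difference of -1.44 from day 4 to day 28 (adjusted p = 9.17e-05). C4A stood at 2.13 at day 4, 2.55 at day 10 and -2.58 at day 28, a difference of -4.71 from day 4 to day 28 (adjusted p = 1.79e-07) and -5.14 from day 10 to day 28 (adjusted p = 7.82e-07). FBLN1 stood at 1.64 at day 4, 1.74 at day 10 and -4.0 at day 28, a difference of -5.64 from day 4 to day 28 (adjusted p = 7.27e-07) and -5.74 from day 10 to day 28 (adjusted p = 3.23e-06). TGM2 stood at 0.58 at day 4, -2.51 at day 10 and -4.76 at day 28, a difference of -5.34 from day 4 to day 28 (adjusted p = 1.02e-08) and -3.09 from day 4 to day 10 (adjusted p = 3.08e-06). LBP stood at 5.34 at day 4, 2.08 at day 10 and -3.83 at day 28, a difference of -9.17 from day 4 to day 28 (adjusted p = 2.11e-07) and -5.91 from day 10 to day 28 (adjusted p = 3.31e-05); with replicate 2 as the sole control the change at day 28 did not pass (adjusted p = 0.0554). EXOC3L4 stood at -2.53 at day 4, -3.21 at day 10 and 1.75 at day 28, a difference of 4.28 from day 4 to day 28 (adjusted p = 3.37e-07) and 4.96 from day 10 to day 28 (adjusted p = 1.24e-06). CCL5 stood at -1.87 at day 10 and 1.04 at day 28, a difference of 2.91 from day 10 to day 28 (adjusted p = 0.000915); with replicate 2 as the sole control the changes at day 10 and day 28 did not pass (adjusted p = 0.0949 and 0.136).

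Fibroblast replicate 2 stood apart from replicates 1 and 3, with chi-square per degree of freedom 308 and 414 against 4.15 for replicates 1 and 3; day 4 replicate 3 stood apart too (124 and 93.4 against 20, rho with gene length 0.297), and the deviations of fibroblast replicate 2 correlated with those of replicate 3 at days 4, 10 and 28 at 0.394, 0.323 and 0.230. Induced neurons in fibroblast replicate 2, by mixing or by label, would need a share of 0.894 for its most counted gene, while the median share over 36 neuronal genes was -0.00147. A few genes taking most of the counts would shift the rest together, while log2 ratios of replicate 2 to 1 spread 4.96 times as widely as those of 3 to 1 (SD 0.973 against 0.196). In fibroblast replicate 2 a trend with gene length was near 0 (Spearman's rho 0.0156). A difference in culture or in the library of another kind stays open and may explain the pattern, and no biological explanation was tested, since the design names none.

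Some fibroblast genes were still counted at day 28, COL1A1 at 13.6% of its fibroblast level. A constant share of unchanged fibroblast RNA would keep all of them near that percent, while the third lowest of 26 stood at 1.56% (the lower quartile, the criterion that had not decided, stood at 6.88%). The choice of control library does not account for it, since the lower of the 2 COL1A1 percents was 12.4% (with replicates 1 and 3) and the other 16.7% (with replicate 2). Unconverted cells with changed expression, or lasting expression in converted cells, may both explain it and were not tested.

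TYRP1, a pigment gene, was counted in fibroblast replicates 1, 2 and 3 at 148, 107 and 154 CPM, and PMEL at 0.750, 6.26 and 0.615 CPM. Melanocytes would bring other abundant pigment genes, and in replicates 1 and 3 the highest of 4 others reached at most 0.506% of TYRP1, which argues against them there. In replicate 2 PMEL reached 5.86%, a value the test leaves undecided, so melanocytes in that culture stay open. The criterion that had not decided was the median of 6 other melanocyte genes, 1.12% (MITF 6.71%). Expression of TYRP1 by the fibroblasts may explain it and was not tested; the labels name no sort or gate.

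The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. The other 6 libraries stayed in the edgeR fit. In the order of the report, 1, 1, 1, 1 and 1 splits, the real one included, called as many genes as the real one. The other splits called 0 genes (at most 4297, 3979, 2572, 731 and 170 at an unadjusted p under 0.05). The real ones called 10627, 11335, 12619, 1336 and 5027. Each other split mixes both groups, so real differences become spread. Their gene and list counts do not measure chance. For lists by camera, 3, 1, 2, 2 and 1 splits called as many, with 21, 19, 18, 16 and 14 in the highest of the others against 19, 22, 18, 16 and 19 in the real ones.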

How the results depend on the processing

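Tests with fibroblast replicate 2 as the sole control, with the 9 induced-neuron libraries alone, and between days without fibroblast replicate 2 were chosen only after the result was seen. Most results kept their direction and their side of the threshold. For single genes named in the text this held in 3456 pairs of a result and an alternative, while 62 no longer passed, 6 newly passed and 21 changed direction. For lists called or described it held in 1602 pairs, 88 no longer passed, most of them with an estimated correlation, 10 newly passed and 2 changed direction. With no filter 7, 4, 5, 3 and 3 lists in all were newly called in the 5 comparisons. Counts of changed genes stayed within 1.5 times the reported count in 60 of 72 cases, and the overlap of days 4 and 28 in all 16, at 8331 to 11935 genes with 1 library left out.

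With 1 library left out, the count of changed genes ran from 9553 to 13573 at day 4, 10353 to 13960 at day 10 and 11966 to 14803 at day 28 against fibroblasts. The highest of each came without fibroblast replicate 2. It ran from 653 (without day 10 replicate 1) to 3554 (without fibroblast replicate 2) for day 10 against day 4, and from 3324 (without day 10 replicate 2) to 8181 (without fibroblast replicate 2) for day 28 against day 10. The first of these 2 was 2184 with DESeq2, 2072 in a fit of the 6 libraries compared and 3169 in the 9 induced-neuron libraries. The second was 9756 in the 6 and 7687 in the 9. Both lack fibroblast replicate 2, whose removal alone raised both counts above those of the 9. The cause was not tested further, nor for DESeq2. With an estimated correlation, 5, 7, 9, 4 and 7 lists changed in the 5 comparisons in the order of the report, against 19, 22, 18, 16 and 19. The cause was not tested.

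Some log2 changes changed sign. With fibroblast replicate 2 as the sole control, the log2 change was 0.0112 for DLG4, 0.93 for FBLN2 and 0.49 for SPARC at day 4; 0.0858 for DLX2 at day 10; 0.17 for DLX2 at day 28. With library-size scaling, the log2 change was 0.00826 for TUBB3 and 0.0681 for COL1A1 from day 4 to day 10. On the deposited TPM, the log2 change was 0.0174 for TUBB3 and 0.0412 for COL1A1 from day 4 to day 10. With DESeq2 size factors, the log2 change was 0.0198 for COL1A1 from day 4 to day 10 and 0.0266 for TUBB3 from day 10 to day 28. With DESeq2, the log2 change was 0.0199 for COL1A1 from day 4 to day 10 and 0.0266 for TUBB3 from day 10 to day 28. With 1 library left out they ran from -0.28 to 0.16 for TUBB3, -0.0482 to 0.0893 for PTBP1 and -0.12 to 0.0694 for COL1A1 from day 4 to day 10 and -0.0655 to 0.0318 for TUBB3 from day 10 to day 28. The camera direction turned for interferon response and lysosome lists at day 28 with fibroblast replicate 2 as the sole control, at median log2 changes of 0.42 and 0.75. The cause was not tested.

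With a block for the replicate number, 10080, 10783, 12253, 899 and 4210 genes changed, and 20, 22, 18, 16 and 19 lists. Deviations of 18 same-number pairs across groups correlated at -0.427 to 0.290, 5 above 0.1. Days 4 and 28 had 0.268, 0.0817 and 0.290, so pairing stays open. Depth, spread and 3 libraries per group together limit single genes: in the simulated data edgeR called 1 of 50 genes changed 1.5-fold, and genes at 0 to 3 counts in a group have bounds or wide intervals.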

Other observations

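Tests with fibroblast replicate 2 as the sole control were chosen only after the result was seen. No list of other cell types in this paragraph was called at day 28 against fibroblasts. Of 12 monoaminergic genes tested, 8 rose, 3 fell and 1 did not pass (camera adjusted p = 0.279), and LMX1B rose from 0 to 12.5 ± 0.734 CPM (at least 184-fold). Of 9 astrocyte genes tested, 5 fell, 3 did not pass and 1 rose (camera adjusted p = 0.0958, but 0.0328 with no filter). Of 8 epithelial and keratinocyte genes tested, 4 rose, 2 fell and 2 did not pass (camera adjusted p = 0.350). Of 5 melanocyte genes tested, 2 rose, 2 did not pass and 1 fell (camera adjusted p = 0.404). Of 4 macrophage and leukocyte genes tested, 3 fell and 1 did not pass (camera adjusted p = 0.392). Of 5 endothelial genes tested, 2 fell, 2 did not pass and 1 rose (camera adjusted p = 0.279). Of 5 adipocyte genes tested, 3 rose, 1 fell and 1 did not pass (camera adjusted p = 0.279). Of 9 chondro-osteogenic genes tested, 5 did not pass, 2 rose and 2 fell (camera adjusted p = 0.761). Of 10 skeletal muscle genes tested, 7 rose and 3 did not pass (camera adjusted p = 0.156), and ACTA1 rose from 0.355 ± 0.159 to 25.2 ± 0.650 CPM (log2 change 6.09 ± 0.26). At day 4 the skeletal muscle list was called (camera adjusted p = 0.0465; 0.218 with estimated correlation), and the camera call ended with library-size scaling, with fibroblast replicate 2 as the sole control and without any 1 of fibroblast replicates 2 and 3 and day 4 replicate 1 (adjusted p = 0.0174 to 0.218 over 14 alternatives). With edgeR the adjusted p of the genes valued here was at most 8.73e-09.

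Nor were these lists of general processes. Of 15 reported miR-9 and miR-9* targets tested, 8 fell, 5 rose and 2 did not pass (camera adjusted p = 0.316), and NR2E1 rose from 0.0565 ± 0.050 to 31.2 ± 3.48 CPM (456-fold, interval 156 to 2215). Of 15 interferon response genes tested, 7 did not pass, 6 fell and 2 rose (camera adjusted p = 0.392). Of 22 cholesterol synthesis genes tested, 11 fell, 8 did not pass and 3 rose (camera adjusted p = 0.189, but 0.0276 with no filter). Of 20 lysosome genes tested, 9 did not pass, 6 rose and 5 fell (camera adjusted p = 0.662). The edgeR adjusted p of NR2E1 was 3.39e-10. At day 10 against fibroblasts, of 17 cAMP response genes tested, 10 fell, 5 rose and 2 did not pass (camera adjusted p = 0.0486; 0.472 with estimated correlation), and the camera call ended in a fit of the 6 libraries compared, with fibroblast replicate 2 as the sole control and without any 1 of day 10 replicates 1 and 2 (adjusted p = 0.00315 to 0.472 over 14 alternatives).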
